A study of Xenopus laevis with 37 samples.

How the data were processed

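The deposited table, per the labels' processing notes, holds transcript abundances in TPM that the authors made from RNA-seq reads with FastQC, Trimmomatic and RSEM. No version of these tools and no genome build is given. Per the labels' protocols, RNA was taken at stage NF20 with a Nucleo-spin kit, libraries were TruSeq stranded mRNA, and replicates were independent. The values fit this unit, since all 37 columns sum close to a common total. TPM keeps no read counts, so library depth and counting error are unknown. The table has 40271 features and 1 empty line, and all 37 value columns were used. Of the columns 33 were matched to a sample by their names, and 4 (heated and unheated hindgut libraries) only to their group, since their numbers do not match the sample titles. The tissue field of the hindgut mesoderm samples says endoderm, and these were grouped by title and source name. The genotype field says wild type also for the transgenic embryos, and no heated sample without the transgene is in the series.

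Values were taken as log2(TPM + 1), keeping the 28863 features (71.7%) with at least 1 TPM in at least 2 libraries. One linear model with 15 group means was fitted to all 37 libraries with limma 3.58.1 in R 4.3.3, with the trend option for the variance prior (22 residual and 4.21 prior degrees of freedom). Each comparison is a contrast of group means, and 3 interactions subtract the foregut from the hindgut effect. A gene is called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors after ± are SD between libraries and SE is the standard error of the log2 difference. Log2 differences of genes near 0 TPM depend on the pseudocount, so for these the TPM is given. The genome holds 2 copies of many genes, written .L and .S, and these were tested apart (7104 names had both). A model ID alone names 17180 of the features.

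Gene lists were written before the data were examined, 21 in all: foregut endoderm, hindgut and tail bud, Hox groups 1 to 5 and 6 to 13, Wnt, BMP, Nodal and TGF-beta, FGF, retinoic acid, endoderm, lateral plate, blood, paraxial mesoderm, notochord, kidney, neural plate, neural crest, epidermis, heat shock, p53 and cell death, and cell cycle. They overlap, the cdx genes being in several. Each was tested with camera in limma at a preset correlation between genes of 0.01 and again with an estimated correlation, with p adjusted over the lists of a comparison. Counts in a list use the adjustment over all genes, and "adjusted over the list alone" uses only its members. Sets of regional or BIO-responsive genes, called and at least 2-fold changed, were always taken from libraries other than those tested. Genes shared by both inhibitors were compared with 50 simulations in which the treatments had no effect and the vehicle was shared, and 50 more with a correlation of 0.411 between same-number libraries.

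The rule for named genes, also written before the data were examined, has 3 parts. First, dkk1, and in the perturbations axin2, sp5, cdx1, cdx2, cdx4, hhex, nr5a2, id3, szl, bambi and msx1, are candidates in every comparison. Second come the largest changes in each direction among called genes with a symbol, at least a 2-fold change, a mean of at least 5 TPM in the higher group and no overlap between the groups: 10 for hindgut against foregut vehicle, 6 for treatments and 4 for the rest, with the other homeolog. Interactions need no such separation. Lastly, up to 4 members of a list with the smallest p serve as examples. The text prints a part of these, and 3 genes are not reported here.

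Whether replicate numbers pair libraries was checked on residuals. In the inhibitor experiment the 21 pairs of libraries with the same number in 2 groups had correlations of 0.312 to 0.557, and each was the best match, so values with the number as a block are given beside results they change. Elsewhere 10 pairs had 0.102 to 0.502. The alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios scaling, homeologs summed, the replicate block, a fit to the groups compared alone and each library left out in turn. Added after seeing the data were the number 1 libraries of the inhibitor experiment left out together, the vehicle divided between the inhibitors, FG_endo replicate 1 left out, the germ layer libraries left out, and each library left out in turn for the set medians. A group left with 1 library is assumed to vary like the others.

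The steps were tested on simulated data with the real design. Of genes given a log2 change of 1, limma found 41 of 107 with 3 libraries per group and 25 of 97 with 2. At a change of 2 it found 81 of 93 and 78 of 103. False calls were 8 of 130 and 2 of 105. Of 100 random sets 0 had p under 0.05 with camera, which does not test sets of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads and other files were not analysed.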

Results

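RNA was sequenced from explants of Xenopus laevis gut region at stage NF20, giving transcript abundances scaled to a common sum (TPM) in 37 libraries. The labels give 15 groups. In the inhibitor experiment, embryos were cultured from stage NF12 to NF20 in the vehicle DMSO, in 40 µM DMH1, which blocks BMP type I receptors, or in 60 µM BIO, which blocks GSK3 and so activates Wnt signalling through beta-catenin. Foregut (FG) and hindgut (HG) explants of these embryos make 6 groups with 3 libraries each. The heat shock experiment has foregut and hindgut pieces of embryos that carry a Dkk1 and GFP transgene under a heat shock promoter, with 30 min at 37C followed by 13C, or without heat, with 2 libraries in each of 4 groups. Foregut and hindgut pieces were also separated into endoderm and mesoderm, with 2 libraries in each of 4 groups, and 3 libraries came from dorsal tissue. Library depth is unknown, so no interval or floor for a value of 0 is given. Every library summed to between 999208 and 999778 TPM. Between 15182 and 22769 features reached 1 TPM per library, lowest in FG_endo replicate 1 and highest in FG_DMSO replicate 1. Across genes, replicate libraries of a group had Pearson correlations of 0.915 to 0.978, and no pair of libraries was identical.

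**Figure D1:**
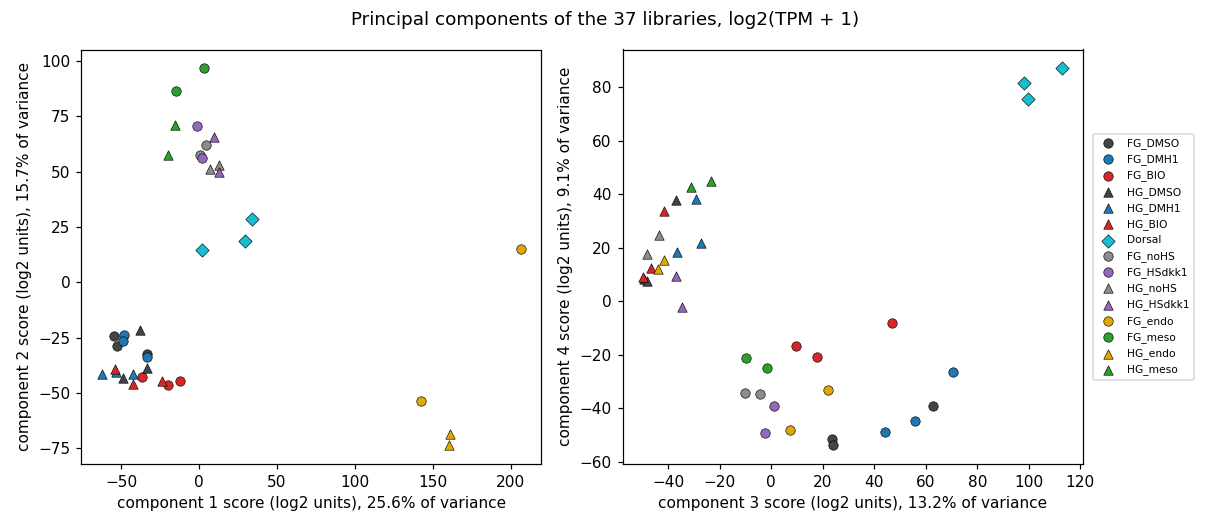
Scores of the 37 libraries on the first 4 principal components of log2(TPM + 1), with foregut groups as circles, hindgut groups as triangles and dorsal tissue as diamonds. Component 1, with 25.6% of the variance, sets the 4 endoderm libraries apart, and component 3, with 13.2%, sets the dorsal libraries apart and separates most foregut from hindgut libraries.

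**Figure D2:**
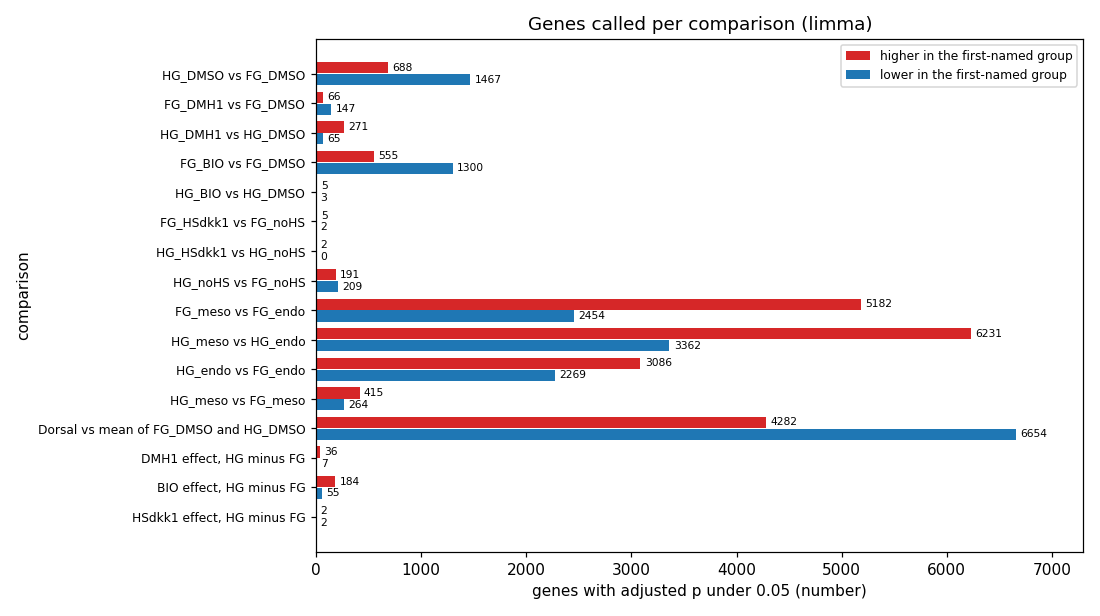
Number of genes with adjusted p under 0.05 in each of 16 comparisons, red bars for genes higher and blue bars for genes lower in the group named first or, for an effect, in the hindgut minus the foregut. The counts run from 2 for Dkk1 heat shock in the hindgut to 10936 for dorsal tissue.

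The vehicle groups ask which genes separate hindgut from foregut at this stage (n = 3 libraries each). The caudal-type homeobox genes, which drive posterior identity, were among the largest hindgut-high genes. The level of cdx4.L was 239.6 ± 74.3 TPM (SD) in HG_DMSO and 1.92 ± 2.01 TPM in FG_DMSO. That of cdx1.S was 169.1 ± 44.2 and 2.02 ± 0.803 TPM, and that of cdx2.S 243.5 ± 50.7 and 6.22 ± 5.25 TPM. The presomitic genes msgn1.L (91.1 ± 32.7 against 1.18 ± 0.775 TPM) and tbx6.L (87.5 ± 79.7 against 0.993 ± 0.675 TPM) and the BMP target ventx3.2.S (75.6 ± 22.3 against 0.917 ± 0.525 TPM) were also higher in hindgut. Among the largest foregut-high genes, from foregut to hindgut agr2.L fell from 2596 ± 529 to 16.4 ± 2.86 TPM, and ag1.S from 1636 ± 491 to 28.3 ± 4.07 TPM. The homeobox gene pitx1.L fell from 105.3 ± 24.5 to 0.787 ± 0.250, and otx2.L from 59.1 ± 30.6 to 0.0767 ± 0.0666. The myeloid genes mpo.S (478.3 ± 99.1 against 9.38 ± 13.8 TPM) and spib.L (167.4 ± 24.1 against 1.63 ± 1.86 TPM) fell likewise.

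Of 59 hindgut and tail bud genes, 48 were higher in HG_DMSO and 2 lower, and 9 did not pass (median log2 fold 3.51, adjusted p = 1.75e-93, or adjusted p = 1.2e-05 with an estimated correlation). Of 41 Hox genes of paralog groups 6 to 13, which pattern the trunk and tail, 36 were higher and none lower (median 3.51, adjusted p = 9.21e-93), with hoxa7.L at 85.2 ± 20.4 against 0.323 ± 0.186 TPM and hoxb6.S at 35.3 ± 19.1 against 0.05 ± 0.0866 TPM. Hox groups 1 to 5 had 20 higher and 1 lower of 30 (adjusted p = 5.61e-25), among them hoxc4.L at 38.5 ± 18.8 against 0.233 ± 0.404 TPM. Of 47 Wnt feedback and target genes 17 were higher and 2 lower (adjusted p = 1.69e-18), while 28 did not pass. Adjusted over the list alone the 4 counts became 48 and 2, 38 and 0, 21 and 4, and 22 and 3. Blood and endothelium genes were lower for 18 of 38 and higher for none (adjusted p = 2.47e-12), with fli1.S at 0.137 ± 0.203 TPM in hindgut and 17.5 ± 2.44 in foregut. With the replicate number as a block that list had adjusted p = 0.0519 with an estimated correlation.

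Foregut endoderm genes were lower for 16 of 38 and higher for 2 (median −0.79, adjusted p = 1.39e-07, or adjusted p = 0.0748 with an estimated correlation), with sfrp5.L, a secreted Wnt inhibitor, at 9.43 ± 3.26 TPM in foregut and 0.323 ± 0.178 in hindgut, and hhex.S at 29.0 ± 1.87 and 0.773 ± 1.09. Neural plate genes were lower for 22 of 37 and higher for 2 (adjusted p = 2.02e-14, or adjusted p = 0.0819 with an estimated correlation), among them sox3.S at log2 fold −4.91 (SE 0.39). Without FG_DMSO replicate 1 the lower count of that list was 13. Pronephros genes were lower for 12 of 26, irx1.L being listed at 0 in HG_DMSO (adjusted p = 6.07e-06, or 0.0779 with an estimated correlation). Lateral plate and cardiac genes were lower for 20 of 44 and higher for 7, with the cardiac factor nkx2-5.S at −5.32 and SE 0.32 (adjusted p = 5.48e-07, or 0.111 with an estimated correlation). Of 19 Nodal and TGF-beta genes 5 were lower and 1 higher (adjusted p = 0.0020, or 0.120 with an estimated correlation). BMP target genes had 9 higher and 3 lower of 49, a median of 0.03 and a mean of 0.49 (adjusted p = 5.38e-05, or 0.160 with an estimated correlation), with ventx1.1.L at 4.03 (SE 0.28). Paraxial mesoderm genes had 11 higher and 1 lower of 53, a median of 0 and a mean of 0.54 (adjusted p = 5.77e-06, or adjusted p = 0.268 with an estimated correlation), and without HG_DMSO replicate 1 there were 8 higher and 3 lower. The FGF list, with fgf8.S at −3.57 (SE 0.39), had 6 lower of 25 (adjusted p = 0.0123, or 0.523 with an estimated correlation). That list did not pass without FG_DMSO replicate 1 (0.0605) or HG_DMSO replicate 2 (0.230), nor when only these 6 libraries were fitted (0.190).

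Cell cycle genes were lower for 8 of 66, mcm4.L at −0.71 (SE 0.16) among them (adjusted p = 0.0108, or adjusted p = 0.372 with an estimated correlation), but 1 was lower and adjusted p = 0.15 after median-of-ratios scaling, and the list did not pass without FG_DMSO replicate 1 (0.108) or HG_DMSO replicate 3 (0.144). The 8 became 1, 5, 4 and 3 without FG_DMSO replicate 1 or 2 or HG_DMSO replicate 2 or 3. The other 7 lists did not pass. Of 18 retinoic acid genes 3 were higher and 4 lower, among them cyp26c1.S, which breaks down retinoic acid, at −5.21 (SE 0.41). Of 36 endoderm genes 5 were higher and 7 lower, and of 23 notochord genes 2 were higher and 3 lower (1 lower without FG_DMSO replicate 1 or HG_DMSO replicate 1 or 2). Of 26 neural crest genes 4 were higher and 3 lower, with snai2.S at 2.93 (SE 0.31), and 1 lower without FG_DMSO replicate 1. Of 27 epidermis genes 1 was lower, of 34 heat shock genes none passed, and of 34 p53 and cell death genes 2 were lower, the inhibitor of cyclin-dependent kinases cdkn1a.S at −2.17 (SE 0.30) and cdkn1a.L at −1.44 (SE 0.28). In all, limma called 688 genes higher and 1467 lower of 28863 (adjusted p under 0.05), while 1443 would pass unadjusted p under 0.05 by chance and 5018 did. The median of all genes lay at −0.12, and after median-of-ratios scaling at 0.01, with 884 higher and 1006 lower. Fitting only these 6 libraries left 841 genes, and leaving out the number 1 libraries of the inhibitor experiment left 1278.

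The DMH1 comparison in foregut asks which genes of the explants depend on BMP signalling (n = 3 libraries each in FG_DMH1 and FG_DMSO). Genes known as direct BMP targets and feedback inhibitors fell. The secreted BMP modulator szl.L fell from 256.5 ± 145.9 TPM to 15.6 ± 10.8, and the receptor decoy bambi.L fell from 223.1 ± 49.4 to 57.9 ± 5.99 TPM, with bambi.S at log2 fold −1.74 (SE 0.24). Of the 49 BMP feedback and target genes 18 were lower and none higher (median −0.85, adjusted p = 1.86e-43, or 8.44e-05 with an estimated correlation), and adjusted over the list alone 31 were lower and 1 higher. Among them were tbx3.L at −2.72 (SE 0.25), msx2.L at −2.70 (SE 0.29), bmp7.1.S at −1.92 (SE 0.20) and msx1.S at −1.97 (SE 0.31). The other msx1 homeolog, msx1.L, was at −1.21 (SE 0.32, adjusted p = 0.0794), and passed with the replicate number as a block (adjusted p = 0.0106). The known target id3 did not pass, at −0.46 (SE 0.23) for id3.L and −0.53 (SE 0.19) for id3.S.

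Blood genes and single factors of other tissues fell as well. The T-box gene tbx20.L, which acts in heart precursors, fell from 70.3 ± 8.12 to 7.16 ± 0.413 TPM, hand2.L from 8.03 ± 2.28 to 0.523 ± 0.455 TPM, dlx2.S from 34.9 ± 11.8 to 1.53 ± 0.535 TPM and gprc5a.L from 26.2 ± 13.1 to 0.27 ± 0.0557 TPM. Blood and endothelium genes were lower for 8 of 38 and for 15 adjusted over the list alone, with none higher (median −0.58, adjusted p = 1.94e-15, or adjusted p = 0.0032 with an estimated correlation). The blood stem cell factor tal1.S was at −2.90 (SE 0.42) and the myeloid factor cebpa.S at −1.53 (SE 0.27). The count of 8 became 5 without FG_DMSO replicate 2 or 3 or FG_DMH1 replicate 1 or 3. Of 44 lateral plate and cardiac genes 6 were lower, the list having a median of 0.31 and a mean of −0.09 (adjusted p = 0.584), and 3 were lower without FG_DMSO replicate 3 or FG_DMH1 replicate 1. Epidermis genes tp63.L (−1.60, SE 0.23) and tp63.S (−1.32, SE 0.20) were lower too. That list had 3 lower of 27 (adjusted p = 7.36e-04, or adjusted p = 0.449 with an estimated correlation), and adjusted p = 0.096 when only these 6 libraries were fitted.

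A part of the kidney and neural genes rose. The pronephros gene pax8.L rose from 2.47 ± 1.38 to 44.9 ± 20.4 TPM and lmx1b.1.L from 1.45 ± 1.30 to 27.5 ± 12 TPM. The neurogenic factor neurog1.L rose from 1.18 ± 0.375 to 15.3 ± 5.33 TPM and neurod1.S from 0.697 ± 0.898 to 7.52 ± 3.33 TPM. Of 26 pronephros genes 2 passed, pax8.L and pax8.S, and 7 adjusted over the list alone (median 0.56, adjusted p = 4.18e-09, or adjusted p = 0.035 with an estimated correlation). Without FG_DMSO replicate 1 there were 4. Of 37 neural plate genes 5 were higher, 10 adjusted over the list alone and 9 with the replicate number as a block (median 0.75, adjusted p = 1.48e-19, or adjusted p = 0.0509 with an estimated correlation, which was 0.0276 with the block). Their count was 2 to 10 with 1 library left out, 2 without FG_DMSO replicate 3, 3 without FG_DMSO replicate 2 or FG_DMH1 replicate 1 or 3, and 10 without FG_DMSO replicate 1. None of 66 cell cycle genes passed limma, though 5 were higher adjusted over the list alone (median 0.25, adjusted p = 1.45e-09, or adjusted p = 0.0466 with an estimated correlation, which was 0.0694 with the block). The Wnt list did not pass (1 higher and 3 lower of 47, median −0.08, adjusted p = 0.0846). It leaned lower and passed with a pseudocount of 0.1 (adjusted p = 0.0237), with a filter at 5 TPM (0.0246), without the number 1 libraries (0.00843), and without FG_DMSO replicate 2 (0.0476) or FG_DMH1 replicate 1 (0.00639). Of its members axin2.L was at −0.31 (SE 0.33) and did not pass, while sp5.L rose from 1.05 ± 0.677 to 10.1 ± 8.40 TPM, and did not pass without the number 1 libraries (adjusted p = 0.0748). Of cdx2.L, 8.43 ± 4.89 TPM fell to 1.90 ± 0.491, a call lost without FG_DMSO replicate 3 (0.0982) and with homeologs summed (0.0805).

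In all 66 genes were higher and 147 lower in FG_DMH1, and 185 and 312 with the replicate number as a block. A fit to these 6 libraries alone called 2, tbx20.L and bmp7.1.L. The count of 213 was 359 without FG_DMSO replicate 1, 115 without FG_DMSO replicate 3, 130 without FG_DMH1 replicate 1 and 138 without FG_DMH1 replicate 3. With a pseudocount of 0.1 it was 99, with 5 it was 372, and with homeologs summed it was 121.

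The DMH1 comparison in hindgut asks the same of the hindgut (n = 3 libraries each in HG_DMH1 and HG_DMSO). The BMP targets fell here too, with bambi.L from 222.0 ± 42.8 to 67.0 ± 9.99 TPM, bmp7.1.S at log2 fold −1.84 (SE 0.20), bmp4.L at −1.33 (SE 0.21) and tbx3.L at −1.80 (SE 0.25). Of 49 genes of the BMP list 17 were lower and none higher, and 27 lower and 2 higher adjusted over the list alone (median −0.88, adjusted p = 1.48e-38, or adjusted p = 1.88e-04 with an estimated correlation). The 17 became 10 without HG_DMSO replicate 2 or 3 or HG_DMH1 replicate 1, and 11 without HG_DMH1 replicate 3. The secreted modulator szl.L fell from 234.8 ± 103.5 to 19.7 ± 8.88 TPM, a call lost without HG_DMSO replicate 2 (adjusted p = 0.0579) or HG_DMH1 replicate 1 (0.0582). Neither msx1 homeolog passed, msx1.S standing at −1.0 (SE 0.31, adjusted p = 0.153, and 0.049 with the replicate number as a block).

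More genes rose than fell in hindgut, with genes of intermediate and paraxial mesoderm among the largest. The kidney gene pax8.L rose from 0.313 ± 0.376 to 42.7 ± 23.5 TPM, lhx1.S from 3.36 ± 0.531 to 36.4 ± 10.7 TPM, and aldh1a2.L, which makes retinoic acid, from 19.8 ± 7.97 to 194.7 ± 5.1 TPM. Some somite and presomitic genes rose as well: tbx6r.L from 1.11 ± 1.03 to 38.4 ± 23.9 TPM, tcf15.L from 2.03 ± 0.724 to 18.7 ± 6.81 TPM and the myogenic factor myf5.S from 1.19 ± 1.09 to 14.3 ± 4.09 TPM. Of 26 pronephros genes 12 were higher, and 16 adjusted over the list alone (median 1.35, adjusted p = 1.52e-25, or adjusted p = 1.88e-04 with an estimated correlation), a count that was 7 without HG_DMSO replicate 2 or HG_DMH1 replicate 3. Of 18 retinoic acid genes 2 were higher, aldh1a2.L and aldh1a2.S (adjusted p = 1.24e-05, or adjusted p = 0.0173 with an estimated correlation), and 4 were higher without HG_DMSO replicate 1 or with the replicate number as a block (0.0578 with an estimated correlation). Paraxial mesoderm genes were higher for 10 of 53 and 17 adjusted over the list alone (adjusted p = 1.08e-11, or adjusted p = 0.114 with an estimated correlation). The 10 became 18 without HG_DMSO replicate 1, and 6 without HG_DMSO replicate 3 or HG_DMH1 replicate 1. Of 44 lateral plate genes 10 were higher and 3 lower (adjusted p = 1.46e-04, or adjusted p = 0.275 with an estimated correlation). The higher count was 6 without HG_DMSO replicate 2 or HG_DMH1 replicate 3, the lower 1 without HG_DMH1 replicate 1, and adjusted p = 0.058 in a fit to these 6 libraries.

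A part of the blood genes fell. The endothelial factor etv2.L fell from 33.9 ± 5.02 to 2.52 ± 1.07 TPM, tal1.S from 9.29 ± 5.08 to 0.193 ± 0.104 TPM and gfi1.L from 9.11 ± 4.09 to 0.417 ± 0.244 TPM. Of the 38 genes of that list 6 were lower and 1 higher, and 8 and 3 adjusted over the list alone (median −0.30, adjusted p = 8.38e-10, or adjusted p = 0.0173 with an estimated correlation, which was 0.0609 with the block). Of 30 Hox genes of groups 1 to 5, 3 were higher, hoxb2.S, hoxb2.L and hoxa3.L, with 12 adjusted over the list alone and 8 with the block (adjusted p = 1.41e-11, or adjusted p = 0.0735 with an estimated correlation). None passed without HG_DMSO replicate 2 or HG_DMH1 replicate 2 or 3, and 1 without HG_DMH1 replicate 1. FGF feedback genes were higher for 3 of 25, 11 adjusted over the list alone and 6 with the block (adjusted p = 1.72e-13, or adjusted p = 0.0735 with an estimated correlation). The phosphatase dusp6.L (1.70, SE 0.30) was 1 of them, with 5 higher without HG_DMSO replicate 1, and fgf8.S and fgf8.L did not pass without HG_DMSO replicate 2 (0.261 and 0.310). Wnt antagonist dkk1.L, itself a Wnt target, rose from 0.683 ± 0.761 to 9.60 ± 4.14 TPM. The posterior genes cdx1, cdx2 and cdx4 did not pass, cdx2.S standing at 0.13 (SE 0.44), and axin2.L was at −0.05 (SE 0.33).

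DMH1 in hindgut raised 271 genes and lowered 65, and 549 and 120 with the replicate number as a block, while a fit to these 6 libraries alone called 34, among them etv2.L, tbx3.L, lhx1.L and lhx1.S. The total of 336 was 140 without HG_DMSO replicate 2, 221 without HG_DMSO replicate 3, 202 without HG_DMH1 replicate 1 and 168 without HG_DMH1 replicate 3. It was 217 with a pseudocount of 0.1 and 203 with homeologs summed. Of the genes called in foregut and in hindgut, 51 were called in both with the same direction, against 0.951 expected by chance, and none in opposite directions.

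The BIO comparison in foregut asks what activation of Wnt signalling does to foregut cells (n = 3 libraries each in FG_BIO and FG_DMSO). Direct Wnt targets rose. The zinc finger factor sp5.L rose from 1.05 ± 0.677 to 111.8 ± 18.6 TPM, the feedback inhibitor axin2.L from 7.06 ± 2.24 to 71.6 ± 13.2 TPM, and wnt10a.L from 0.28 ± 0.123 to 18 ± 0.86 TPM. The posterior genes cdx2.S (6.22 ± 5.25 to 109.1 ± 29.4 TPM), cdx4.L (1.92 ± 2.01 to 33.2 ± 11.6 TPM) and cdx1.S (2.02 ± 0.803 to 25.6 ± 10.6 TPM) rose too. Of the 47 genes of the Wnt list 23 were higher and 2 lower, and 31 and 2 adjusted over the list alone (median 1.19, adjusted p = 2.80e-31, or 3.64e-04 with an estimated correlation). Hox genes of groups 1 to 5 were higher for 9 of 30, hoxc4.S rising from 1.06 ± 0.900 to 9.19 ± 2.14 TPM (adjusted p = 1.55e-08, or 0.207 with an estimated correlation). In groups 6 to 13, 5 of 41 were higher, hoxa7.L, hoxc8.L, hoxc8.S and hoxc6.S among them, at 5.1 ± 1.85, 5.54 ± 1.81, 5.54 ± 1.60 and 5.81 ± 1.77 TPM (list median 0, mean 0.34, adjusted p = 2.10e-04, or adjusted p = 0.563 with an estimated correlation). The hindgut and tail bud list had 9 higher and 1 lower of 59, a median of 0.02 and a mean of 0.41 (adjusted p = 9.71e-06, or 0.394 with an estimated correlation).

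Blood genes and single factors of other tissues fell. The homeobox gene pitx1.L fell from 105.3 ± 24.5 to 0.727 ± 0.594 TPM, the retinoic acid hydroxylase cyp26c1.S from 90.4 ± 35.2 to 0.87 ± 0.809 TPM and the cardiac factor tbx20.L from 70.3 ± 8.12 to 1.89 ± 0.837 TPM. Myeloid genes fell with them, spib.L from 167.4 ± 24.1 to 2.48 ± 1.17 TPM, mpo.L from 43.8 ± 17.7 to 0.267 ± 0.326 TPM and cebpa.L from 96.8 ± 12 to 3.93 ± 0.835 TPM. Of 38 blood and endothelium genes 21 were lower and none higher, and 24 and 0 adjusted over the list alone (median −1.29, adjusted p = 6.93e-25, or 3.21e-04 with an estimated correlation). Of 44 lateral plate and cardiac genes 13 were lower and 4 higher, nkx2-5.S at log2 fold −3.02 (SE 0.32) among the lower (adjusted p = 0.00761, or 0.482 with an estimated correlation). That list had adjusted p = 0.0506 with the replicate number as a block and 0.232 in a fit to these 6 libraries, and its 4 higher became 1 without FG_DMSO replicate 1 or FG_BIO replicate 2 or 3 and 2 without FG_BIO replicate 1. The BMP ligands bmp7.1.S (−2.52, SE 0.20) and bmp7.1.L (−2.01, SE 0.21) fell. The kinase inhibitor cdkn1a.S was at −2.65 (SE 0.30). The foregut endoderm list did not pass (1 higher and 3 lower of 38, adjusted p = 0.177). Its members hhex.L and hhex.S stood at −1.34 (SE 0.50) and −1.12 (SE 0.51), with adjusted p = 0.123 and 0.234.

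BMP target genes moved in both directions under BIO, 3 higher and 15 lower of 49, and 8 and 20 with the replicate number as a block (median −0.25, adjusted p = 0.00981, or adjusted p = 0.482 with an estimated correlation). The call of that list was lost without FG_DMSO replicate 2 (0.0505), without FG_BIO replicate 1 (0.0632) and in a fit to these 6 libraries (0.132), and the 15 became 6 to 9 without FG_DMSO replicate 2 or FG_BIO replicate 1 or 3, and the 3 higher 5 without FG_DMSO replicate 3. The decoy receptor bambi.S fell by 0.98 (SE 0.24), not passing without FG_DMSO replicate 2 (0.102) or FG_BIO replicate 1 (0.0529), and szl.L fell from 256.5 ± 145.9 to 50.2 ± 36.9 TPM, not passing without FG_DMSO replicate 2 (0.122) or 3 (0.0739) or FG_BIO replicate 1 (0.191). The target msx1.S rose from 46.5 ± 15.9 to 125.2 ± 12.46 TPM, and did not pass in a fit to these 6 libraries. FGF feedback genes were lower for 7 of 25 and 11 with the block (adjusted p = 3.39e-06, or adjusted p = 0.394 with an estimated correlation). The 7 became 4 without FG_DMSO replicate 1 or 3, and 2 without FG_BIO replicate 3. Neural crest genes were higher for 7 of 26 (adjusted p = 8.29e-07, or adjusted p = 0.207 with an estimated correlation), a count of 3 without FG_DMSO replicate 2 or FG_BIO replicate 1 and of 2 without FG_DMSO replicate 3.

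BIO in foregut raised 555 genes and lowered 1300, and 1070 and 2278 with the replicate number as a block. After median-of-ratios scaling, which moved the median of all genes from −0.08 to −0.01, they were 656 and 927, while a fit to these 6 libraries alone called 1114. The count of 1855 was 1175 without FG_DMSO replicate 2 or FG_BIO replicate 1, 1041 without FG_DMSO replicate 3, 1067 without FG_BIO replicate 3 and 1119 without all number 1 libraries. Of 205 genes at least 2-fold higher in unheated foregut than in unheated hindgut, from libraries outside the inhibitor experiment, 101 were lower and 3 higher in FG_BIO (median −1.06, adjusted p = 2.96e-04 with an estimated correlation), and of 186 genes higher in unheated hindgut 37 were higher and 2 lower (median 0.17, adjusted p = 0.0846 with an estimated correlation).

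The BIO comparison in hindgut asks the same where 17 of the 47 Wnt genes stood higher than in foregut under vehicle (n = 3 libraries each in HG_BIO and HG_DMSO). The Wnt targets named did not pass limma. The level of axin2.L was 51.8 ± 1.80 TPM against 36.7 ± 1.90 (log2 fold 0.49, SE 0.33), of sp5.L 14.4 ± 5.50 against 3.37 ± 0.41 TPM (1.76, SE 0.38) and of cdx2.S 326.6 ± 52.0 against 243.5 ± 50.7 TPM (0.43, SE 0.44). With the replicate number as a block axin2.S (1.53, SE 0.31, adjusted p = 0.0721) passed (0.00748), as sp5.L did (0.0271). BMP and blood genes seen to fall in foregut lay below the vehicle without passing, bmp7.1.S at −1.05 (SE 0.20, adjusted p = 0.0525, and 0.013 with the block) and tal1.S at −1.77 (SE 0.42, adjusted p = 0.106, and 0.046 with the block).

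Of 28863 genes 5 were higher, lum.L (1.43 ± 0.941 to 9.36 ± 2.16 TPM), nmd3.L (log2 fold 0.64), rcl1.L (0.51), trmt6.L (0.64) and Xelaev18039044m.g (1.2). The 3 lower were the transcription elongation inhibitor hexim1.L (88.7 ± 17.4 to 33.7 ± 7.23 TPM), the Wnt antagonist sfrp2.S (−1.91) and Xelaev18031387m.g (−1.50). At unadjusted p under 0.05 there were 1795 genes, against 1443 expected. Of the named pair, hexim1.L did not pass without HG_DMSO replicate 1 (0.0883), 2 (0.131) or 3 (0.0601) or HG_BIO replicate 2 (0.170) or 3 (0.165), and lum.L not without HG_DMSO replicate 1 (0.0538) or 2 (0.131) or HG_BIO replicate 2 (0.0726) or 3 (0.15). The count of 8 was 148 with the replicate number as a block, 24 with a pseudocount of 5, 14 without the filter and 0 in a fit to these 6 libraries. With 1 library left out it was 18 without HG_DMSO replicate 1, 1 without HG_DMSO replicate 2, 2 without HG_DMSO replicate 3, 25 without HG_BIO replicate 1, 3 without HG_BIO replicate 2 and 1 without HG_BIO replicate 3. It was 43 without FG_endo replicate 1 and 65 without all germ layer libraries.

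As lists, cell cycle genes had a median of −0.21 with no gene past limma (adjusted p = 4.65e-12, or adjusted p = 0.0627 with an estimated correlation), 10 of 66 lower adjusted over the list alone and 6 with the block. The cyclin ccna1.L was at −1.62 (SE 0.32, adjusted p = 0.0618, and 0.0124 with the block). Lateral plate genes (0 of 44 passing, adjusted p = 1.32e-06, or adjusted p = 0.309 with an estimated correlation) and blood genes (0 of 38, 4 lower adjusted over the list alone, adjusted p = 7.08e-06, or adjusted p = 0.188 with an estimated correlation) leaned lower. Wnt genes leaned higher (median 0.16, 2 of 47 higher adjusted over the list alone, adjusted p = 0.019, or adjusted p = 0.733 with an estimated correlation), a call lost without HG_DMSO replicate 2 (0.182) or HG_BIO replicate 1 (0.685). Hox genes of groups 6 to 13 leaned lower (median −0.33, adjusted p = 1.05e-05, or adjusted p = 0.733 with an estimated correlation), but their median was 0.16 without HG_DMSO replicate 1 (adjusted p = 0.268), and the call was lost without HG_BIO replicate 2 (0.279) or 3 (0.0987). Leaving out HG_DMSO replicate 1 also turned the hindgut and tail bud median from −0.26 to 0.11.

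**Figure D3:**
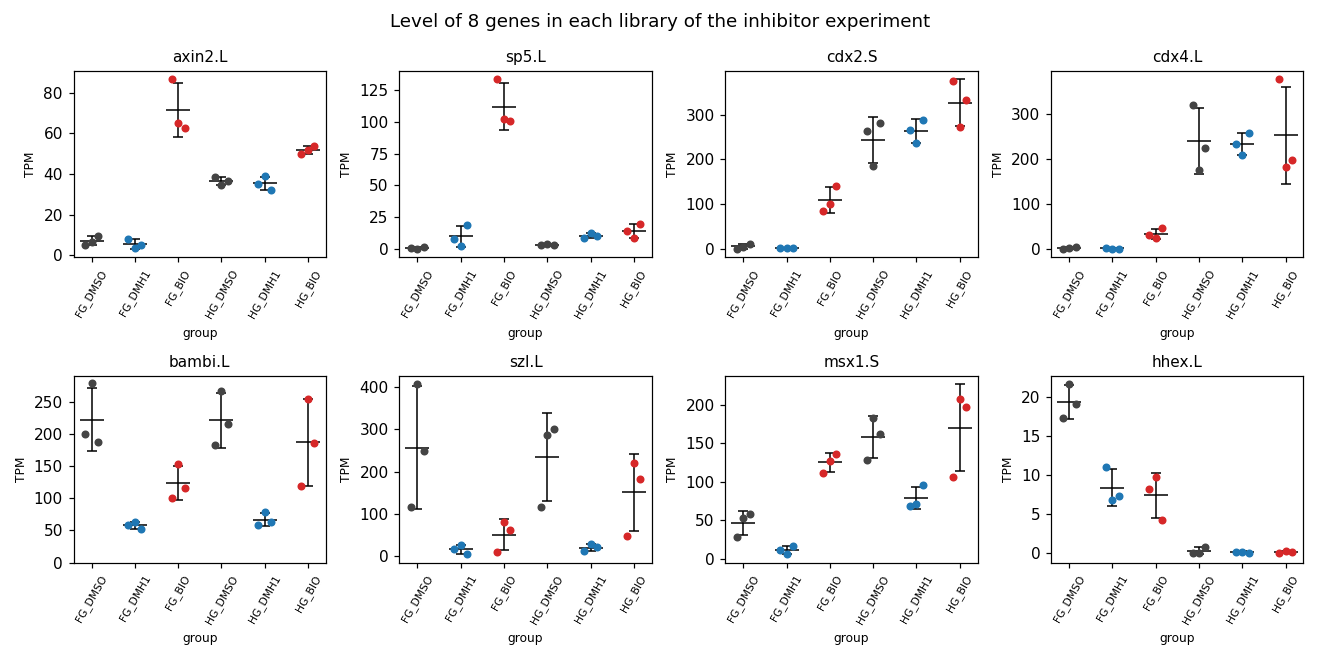
TPM of 8 genes in each library of the 6 groups of the inhibitor experiment, with points for libraries (n = 3 per group) and bars for the mean and SD. The Wnt target axin2.L stands at 7.06 TPM in FG_DMSO, 71.6 in FG_BIO, 36.7 in HG_DMSO and 51.8 in HG_BIO, and bambi.L lies below 80 TPM in every DMH1 library.

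BIO effects in the 2 regions were compared as an interaction, hindgut minus foregut effect (3 libraries in each of 4 groups). Wnt targets had a smaller effect in hindgut, by −4.07 for sp5.L (SE 0.54), −2.95 for cdx2.L (SE 0.42), −3.72 for cdx4.L (SE 0.57) and −2.70 for axin2.L (SE 0.47). Some genes BIO removed from foregut were near 0 in hindgut throughout, so their interaction was positive. For pitx1.L it was 6.59 (SE 0.75), with 105.3 ± 24.5 TPM in FG_DMSO and 0.787 ± 0.250 in HG_DMSO, for cyp26c1.S 5.36 (SE 0.58) and for spib.L 4.79 (SE 0.60). Of 47 Wnt genes 10 had a lower effect in hindgut and none a higher, and 17 and 0 adjusted over the list alone (median −0.84, adjusted p = 5.72e-36, or 2.46e-04 with an estimated correlation). Of 38 blood genes, 18 lower in HG_DMSO than FG_DMSO with less room to fall, 12 had a higher effect and none a lower, and 17 and 0 adjusted over the list alone (median 1.27, adjusted p = 2.46e-23, or 2.46e-04 with an estimated correlation). Hindgut and tail bud genes had 5 lower of 59 (adjusted p = 9.57e-16, or 0.0751 with an estimated correlation). In all limma called 184 genes higher and 55 lower, and after median-of-ratios scaling, which moved the median of all genes from 0.10 to 0.00331, 120 and 49. The total was 381 with the replicate number as a block, 143 with a pseudocount of 0.1 and 158 with homeologs summed. The calls of cdx2.L (adjusted p = 0.0502) and cdx4.L (0.0614) ended in a fit to these 12 libraries.

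The interaction for DMH1 called 36 genes higher and 7 lower, and 1267 genes had unadjusted p under 0.05, below the 1443 expected by chance. The kidney factor lhx1.S, at 3.26 ± 1.2 TPM in FG_DMSO and 2.34 ± 0.170 in FG_DMH1, rose only in hindgut (interaction 3.39, SE 0.50). For gprc5a.L, lost from foregut and near 0 in hindgut throughout, it was 4.41 (SE 0.57). The presomitic gene tbx6r.L had 4.17 (SE 0.63) and foxd4l1.1.S 3.14 (SE 0.56), both not passing with a pseudocount of 0.1 (adjusted p = 0.113 and 0.880) or in a fit to these 12 libraries (0.0904 and 0.140). The neurogenic genes neurog1.L (−2.90, SE 0.40) and neurod1.S (−2.36, SE 0.39) had a lower effect in hindgut, not passing with that pseudocount (0.258 and 0.132). The call of neurog1.L was lost without the number 1 libraries (0.0572), and that of neurod1.S with homeologs summed (0.0653) or in a fit to these 12 libraries (0.270). The BMP list did not pass, with 0 of 49 passing limma, 0 adjusted over the list alone, and a median of 0.20 (adjusted p = 0.113). It passed with a pseudocount of 0.1 (median 0.34, adjusted p = 0.011), without the number 1 libraries (0.25, 0.0418), and without FG_DMSO replicate 1 (0.21, 0.0217) or HG_DMSO replicate 3 (0.27, 0.0447). Of the other lists 13 passed the preset test and none with an estimated correlation (lowest adjusted p = 0.206). The count of 43 was 78 with the replicate number as a block, 10 and 88 with pseudocounts of 0.1 and 5, 26 after median-of-ratios scaling and 21 in a fit to these 12 libraries. It was 27 without FG_DMSO replicate 3, 26 without FG_DMH1 replicate 1, 25 without FG_DMH1 replicate 3, 18 without HG_DMSO replicate 2, 23 without HG_DMH1 replicate 1 and 19 without all number 1 libraries.

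Genes under both inhibitors were compared in foregut, where each effect was taken against the same 3 vehicle libraries. Of the 147 genes that DMH1 lowered, BIO also lowered 98, against 6.62 expected from independent lists. Among them were bmp7.1.S, tbx20.L, tal1.S, tbx3.L and cebpa.S. Neither set of 50 simulations had any such gene, but with no treatment effect they cannot show what a shared vehicle adds to real lists. The 2 effects correlated at 0.386, and at 0.501 when simulated. Of the 66 genes that DMH1 raised 9 were also raised by BIO (1.27 expected), and 4 moved in opposite directions (5.80 expected), msx1.S being 1 of these. With the vehicle libraries divided between the inhibitors, in all 6 ways of 1 and 2, 23 to 61 were lower with both (1.33 to 3.47 expected) and 2 to 7 higher (0.216 to 0.631 expected), while 0 to 41 moved in opposite directions, 41 with FG_DMSO replicate 1 alone for BIO. The 98 became 193 with the replicate number as a block, 159 and 39 with pseudocounts of 5 and 0.1, 65 with homeologs summed, 48 without the number 1 libraries and 2 in fits to the groups alone.

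Foregut libraries labelled Dkk1 heat shock (n = 2) were compared with unheated foregut libraries (n = 2) to ask what the Wnt antagonist Dkk1 changes. The transcript dkk1.L stood at 15.7 ± 1.48 TPM in the heat shock libraries and 18.4 ± 3.52 in the unheated ones (log2 fold −0.20, SE 0.53). No named Wnt or hindgut gene passed limma. The posterior factors cdx2.L (−1.05, SE 0.37), cdx2.S (−1.45, SE 0.54) and cdx4.L (−1.63, SE 0.49), and the retinoic acid enzyme aldh1a2.L (−1.63, SE 0.48), lay below the unheated level with adjusted p of 1. Wnt genes as a list had 0 of 47 passing, 0 adjusted over the list alone and a median of −0.25 (adjusted p = 3.83e-07, or adjusted p = 0.144 with an estimated correlation). Hox genes of groups 1 to 5 had 0 of 30 and a median of −0.47 (adjusted p = 2.20e-11, or adjusted p = 0.125 with an estimated correlation), with hoxb3.S at 4.88 ± 0.424 TPM after heat shock and 10.2 ± 0.163 without. Kidney genes had 0 of 26 and a median of −0.42 (adjusted p = 4.36e-08, or adjusted p = 0.125 with an estimated correlation), lhx1.L being at −1.2 (SE 0.41). The heat shock list had 0 of 34 and a median of −0.00115 (adjusted p = 0.159), with hspa8.L at −0.34 (SE 0.12).

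Sets of genes sorted by their BIO response in the other experiment leaned the opposite way here, with 0 members of either passing limma. The 238 genes raised at least 2-fold by BIO had a median of −0.23 (adjusted p = 4.60e-16, or adjusted p = 0.0148 with an estimated correlation) and the 859 lowered by BIO a median of 0.28 (adjusted p = 4.46e-20, or adjusted p = 0.00814 with an estimated correlation). The latter median ranged from 0.11 without FG_HSdkk1 replicate 1 to 0.45 without FG_HSdkk1 replicate 2. In all 5 genes were called higher, LOC100489362.L (log2 fold 1.60), MGC69088.L (1.22), Xelaev18007944m.g (4.14), Xelaev18015158m.g (1.95) and Xelaev18018961m.g (1.70). The 2 lower were Xelaev18006344m.g (−1.47) and Xelaev18021743m.g (−1.62), all chosen after the values were seen. At unadjusted p under 0.05 there were 524 genes. The count of 7 was 20 without FG_noHS replicate 1, 4 without FG_noHS replicate 2, 3 without FG_HSdkk1 replicate 1, 31 without the filter, 1 with a filter at 5 TPM and 0 in a fit to these 4 libraries.

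In hindgut the same comparison (n = 2 and 2) had dkk1.L at 7.58 ± 0.743 TPM after heat shock and 9.77 ± 5.08 without. Targets of Wnt signalling lay lower without passing limma, axin2.L at −1.04 (SE 0.41), cdx1.L at −1.14 (SE 0.40) and cdx4.L at −1.18 (SE 0.49). As lists they leaned lower: hindgut and tail bud genes had 0 of 59 passing, 1 lower adjusted over the list alone and a median of −0.71 (adjusted p = 1.22e-28, or adjusted p = 0.00774 with an estimated correlation). Wnt genes had 0 of 47 passing, 0 adjusted over the list alone and a median of −0.52 (adjusted p = 3.34e-17, or adjusted p = 0.00774 with an estimated correlation). The 560 genes at least 2-fold higher in hindgut than foregut in the inhibitor experiment had 0 passing and a median of −0.41 (adjusted p = 2.09e-31, or adjusted p = 0.00814 with an estimated correlation). Blood genes had a median of 0.49, with 1 of 38 higher (3 without 1 heated library) and 10 adjusted over the list alone (adjusted p = 1.25e-18, or adjusted p = 0.00214 with an estimated correlation). Among them the myeloid factor spib.L rose from 0.38 ± 0.141 to 23.2 ± 21.6 TPM, a call lost without 1 unheated library (adjusted p = 0.0737) and without 1 heated library (0.211). The foregut gene hhex.L was at 7.67 ± 3.51 TPM after heat shock and 0.530 ± 0.453 without, and did not pass (log2 fold 2.47, SE 0.62, adjusted p = 0.476).

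Only spib.L (log2 fold 3.77) and LOC100489362.L (2.03) passed limma in hindgut, the latter named after the values were seen, and 676 genes had unadjusted p under 0.05. That count was 5 or 0 without 1 of the unheated libraries, 15 without 1 heated library, 25 without the filter, 1 with a filter at 5 TPM, 5 with a pseudocount of 0.1, 10 after median-of-ratios scaling and 0 in a fit to these 4 libraries. For the difference between hindgut and foregut in this response limma called 2 genes higher, Xelaev18006344m.g (1.47) and Xelaev18015913m.g (1.69), and 2 lower, Xelaev18007944m.g (−5.31) and Xelaev18018961m.g (−1.70), named after the values were seen. At unadjusted p under 0.05 there were 301. The hindgut and tail bud median of this difference was −0.50 (0 of 59 passing, adjusted p = 2.23e-08, or adjusted p = 0.303 with an estimated correlation). The 4 became 8 without FG_noHS replicate 1, 1 without FG_HSdkk1 replicate 1, 1 without either unheated hindgut library, 1 without 1 heated hindgut library, 27 without the filter, 1 with a filter at 5 TPM, 1 with a pseudocount of 5 and 0 in a fit to these 8 libraries.

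Unheated hindgut against unheated foregut (n = 2 and 2) shows the regional difference in libraries apart from the inhibitor experiment. The tail bud factor tbx6.L stood at 82.6 ± 8.75 TPM in hindgut and 1.36 ± 1.70 in foregut, and hoxb8.L at 57.2 ± 7.95 and 1.97 ± 0.735. The myeloid genes mpo.S (390.0 ± 13.7 TPM in foregut, 1.67 ± 0.0636 in hindgut) and spib.L (82.4 ± 3.88 and 0.38 ± 0.141) were lower in hindgut. Of 41 Hox genes of groups 6 to 13, 31 were higher and none lower, and 35 and 0 adjusted over the list alone (median 2.61, adjusted p = 9.13e-108, or adjusted p = 1.11e-04 with an estimated correlation). Of 59 hindgut and tail bud genes 40 were higher, 46 adjusted over the list alone (median 2.37, adjusted p = 2.46e-111, or adjusted p = 3.03e-06 with an estimated correlation), among them ventx1.1.L (log2 fold 4.06, SE 0.34). Of 47 Wnt genes 12 were higher, 14 adjusted over the list alone (adjusted p = 3.12e-22, or adjusted p = 0.00208 with an estimated correlation), as cdx1.S (3.60, SE 0.45). Of 53 paraxial mesoderm genes 16 were higher, 27 adjusted over the list alone (adjusted p = 5.57e-37, or adjusted p = 0.00287 with an estimated correlation). The 16 became 6 without FG_noHS replicate 1 and 4 without 1 unheated hindgut library. Of 38 blood genes 8 were lower, 12 adjusted over the list alone (adjusted p = 3.84e-12, or adjusted p = 0.00476 with an estimated correlation).

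In these unheated libraries limma called 191 genes higher in hindgut and 209 lower. Of the 400, 322 were also called between the vehicle groups, all in the same direction, against 15.2 expected from independent lists. The 400 became 245 without FG_noHS replicate 2, 224 without 1 unheated hindgut library and 0 in a fit to these 4 libraries.

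In foregut the layer labelled mesoderm was compared with the layer labelled endoderm (n = 2 and 2). Epidermal genes had the largest differences: the epidermal lectin itln1.L stood at 6928 ± 1314 TPM in FG_meso and 4.63 ± 6.55 in FG_endo, and the keratin krt12.S at 9838 ± 1502 and 12.42 ± 11.7. All 27 epidermal genes were higher in the mesoderm libraries, also adjusted over the list alone (median 5.07, adjusted p = 6.09e-37, or adjusted p = 0.00178 with an estimated correlation). Of 36 endoderm genes 25 were lower and 4 higher (2 higher without FG_meso replicate 1), the same adjusted over the list alone (median −3.20, adjusted p = 1.81e-18, or adjusted p = 0.00178 with an estimated correlation). Among them sox17a.S, which specifies endoderm, stood at 331.4 ± 171.5 TPM in endoderm and 0.475 ± 0.389 in mesoderm. Of 38 foregut endoderm genes 20 were lower and none higher (3 higher without FG_endo replicate 2), the same adjusted over the list alone (median −1.80, adjusted p = 8.03e-12, or adjusted p = 0.0273 with an estimated correlation, which was 0.0909 with the replicate number as a block), as foxa2.S (log2 fold −6.10, SE 0.31). Of 38 blood genes 21 were higher, 24 adjusted over the list alone (adjusted p = 8.00e-05, or adjusted p = 0.177 with an estimated correlation), as slc4a1.S (4.18, SE 0.30), and 12 without FG_meso replicate 1. Of 44 lateral plate genes 14 were higher and 9 lower, 14 and 10 adjusted over the list alone (median 0.0434, adjusted p = 0.994), hand2.L at 17.4 ± 3.19 TPM in mesoderm against 0.260 ± 0.0849. In all 5182 genes were higher and 2454 lower. The sum became 863 in a fit to these 4 libraries.

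In hindgut the mesoderm and endoderm libraries (n = 2 and 2) parted the same way. The lectin itln1.L was at 6013 ± 1217 TPM in HG_meso and 2.45 ± 1.99 in HG_endo and the endodermal darmin.L at 1.16 ± 0.898 and 3896 ± 172.3. Of 27 epidermal genes 26 were higher in mesoderm and 1 lower, the same adjusted over the list alone (median 4.95, adjusted p = 1.00e-26, or adjusted p = 0.00634 with an estimated correlation). Of 36 endoderm genes 27 were lower and 1 higher, 30 and 1 adjusted over the list alone (median −3.09, adjusted p = 8.51e-22, or adjusted p = 0.00134 with an estimated correlation), and of 38 foregut endoderm genes 22 were lower, 24 adjusted over the list alone (adjusted p = 2.01e-11, or adjusted p = 0.0312 with an estimated correlation, which was 0.0971 with the replicate number as a block). Of 53 paraxial mesoderm genes 32 were higher and 2 lower, 34 and 2 adjusted over the list alone (median 2.08, adjusted p = 5.36e-05, or adjusted p = 0.516 with an estimated correlation), tbx6.L standing at 190.4 ± 23.1 and 2.13 ± 1.12 TPM. Hox genes of groups 6 to 13 had 21 of 41 higher in mesoderm and none lower, 24 adjusted over the list alone (adjusted p = 9.69e-05, or adjusted p = 0.564 with an estimated correlation), while cdx1.L was lower (log2 fold −4.22, SE 0.40). In all 6231 genes were higher and 3362 lower, and after median-of-ratios scaling, which moved the median of all genes from 0.11 to 0, 5692 and 4650. A fit to these 4 libraries called 4600 in all.

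**Figure D4:**
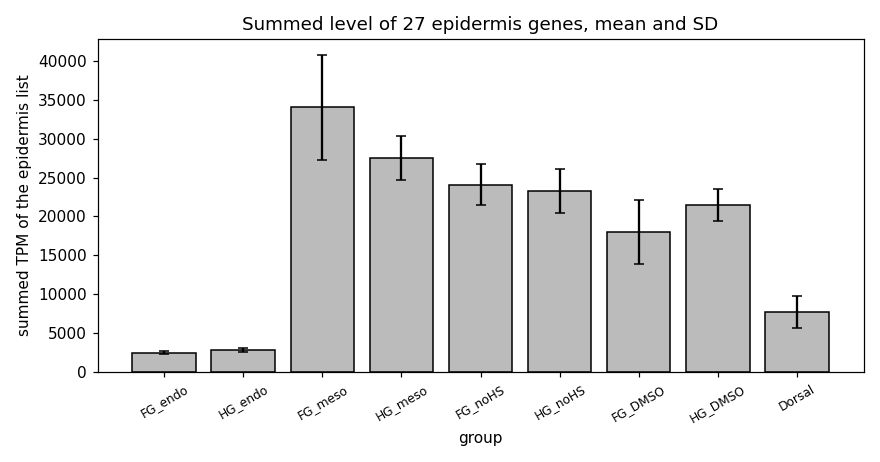
Summed TPM of the 27 epidermal genes in each library, by group. The sum is 34030 ± 6791 in FG_meso, 27500 ± 2862 in HG_meso, 18000 ± 4174 in FG_DMSO and 2488 ± 253.7 in FG_endo (mean ± SD, n = 2 or 3 libraries).

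Endoderm of hindgut was set against endoderm of foregut (n = 2 and 2). The posterior gene hoxc6.L stood at 117.4 ± 2.79 TPM in HG_endo and 0.275 ± 0.389 in FG_endo, the Wnt receptor fzd10.L at 78.8 ± 20.9 and 0.720 ± 0.764, and cdx4.L at 309.4 ± 16.2 and 6.16 ± 2.13. The myeloid gene mpo.S (100.8 ± 44.1 TPM in foregut, 0.135 ± 0.191 in hindgut) and the neural factor sox3.L (71.7 ± 17.1 and 2.16 ± 0.212) were lower. Of 59 hindgut and tail bud genes 37 were higher and 2 lower, 40 and 2 adjusted over the list alone (median 2.15, adjusted p = 1.91e-21, or adjusted p = 0.0747 with an estimated correlation). Of 41 Hox genes of groups 6 to 13, 30 were higher, 32 adjusted over the list alone (median 2.19, adjusted p = 1.65e-21, or adjusted p = 0.127 with an estimated correlation). Of 47 Wnt genes 26 were higher and 3 lower, 28 and 3 adjusted over the list alone (adjusted p = 1.47e-09, or adjusted p = 0.119 with an estimated correlation), and 17 and 0 without FG_endo replicate 1 and 25 and 0 without HG_endo replicate 2. Of 38 foregut endoderm genes 9 were higher and 9 lower, 12 and 9 adjusted over the list alone (median 0.18, mean −0.15, adjusted p = 0.499), but 4 and 8 without FG_endo replicate 1 and 2 and 7 without HG_endo replicate 1, sfrp5.L being lower (log2 fold −3.60, SE 0.36). Of 66 cell cycle genes 18 were lower and 3 higher, 20 and 4 adjusted over the list alone (adjusted p = 1.36e-05, or adjusted p = 0.192 with an estimated correlation), as mcm4.L (−2.54, SE 0.19), the 3 becoming 1 without FG_endo or HG_endo replicate 1, and 9 and 5 without FG_endo or HG_endo replicate 2. In all 3086 genes were higher and 2269 lower. The 5355 became 8617 without FG_endo replicate 2 and 0 in a fit to these 4 libraries.

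Mesoderm of hindgut was set against mesoderm of foregut (n = 2 and 2). The tail bud factor tbx6.L stood at 190.4 ± 23.1 TPM in HG_meso and 0.115 ± 0.163 in FG_meso, hoxb8.L at 103.9 ± 26.6 and 0.170 ± 0.240, and hoxb9.S at 96.8 ± 2.01 and 0.365 ± 0.233. The myeloid genes mpo.S (343.5 ± 59.9 TPM in foregut, 2.00 ± 2.61 in hindgut) and spib.L (121.7 ± 8.42 and 0.585 ± 0.446) were lower. Of 41 Hox genes of groups 6 to 13, 34 were higher, 40 adjusted over the list alone (median 4.2, adjusted p = 2.14e-110, or adjusted p = 9.23e-05 with an estimated correlation). Of 30 Hox genes of groups 1 to 5, 13 were higher, 16 adjusted over the list alone (median 1.34, adjusted p = 4.37e-17, or adjusted p = 0.0229 with an estimated correlation, which was 0.0532 with the replicate number as a block), and 8 without FG_meso replicate 1 or without FG_meso replicate 2. Of 59 hindgut and tail bud genes 42 were higher and 1 lower, 47 and 1 adjusted over the list alone (median 3.43, adjusted p = 4.98e-94, or adjusted p = 1.20e-05 with an estimated correlation). Of 47 Wnt genes 17 were higher and 1 lower, 25 and 3 adjusted over the list alone (adjusted p = 3.89e-22, or adjusted p = 0.00159 with an estimated correlation). Of 38 blood genes 11 were lower, 14 adjusted over the list alone (adjusted p = 1.04e-15, or adjusted p = 0.00159 with an estimated correlation), and 6 without FG_meso replicate 1 or without HG_meso replicate 2. Of 53 paraxial mesoderm genes 19 were higher, 25 higher and 1 lower adjusted over the list alone (adjusted p = 5.86e-18, or adjusted p = 0.039 with an estimated correlation), and 11 without FG_meso replicate 2 or without HG_meso replicate 1.

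Between the mesoderm libraries limma called 415 genes higher in hindgut and 264 lower. Of the 679, 454 were called in the same direction between the vehicle groups and 1 in the opposite direction. The 679 became 363 without FG_meso replicate 1, 441 without FG_meso replicate 2, 1143 with the replicate number as a block, 1039 without FG_endo replicate 1 and 0 in a fit to these 4 libraries.

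Dorsal tissue (n = 3) was compared with the mean of both vehicle gut groups (n = 3 each). Among the largest differences cardiac actin actc1.L stood at 2561 ± 129.2 TPM in Dorsal and 2.41 ± 3.34 in HG_DMSO, and was listed at 0 in FG_DMSO. Of 53 paraxial mesoderm genes 49 were higher and none lower, 51 and 0 adjusted over the list alone (median 3.85, adjusted p = 2.64e-47, or adjusted p = 0.00287 with an estimated correlation). Of 37 neural plate genes 34 were higher and none lower, 35 and 0 adjusted over the list alone (median 3.05, adjusted p = 5.19e-27, or adjusted p = 0.0406 with an estimated correlation), among them egr2.L, a hindbrain gene (log2 fold 4.01, SE 0.27). Of 23 notochord genes 19 were higher and 1 lower, 19 and 2 adjusted over the list alone (median 2.18, adjusted p = 4.02e-11, or adjusted p = 0.054 with an estimated correlation), as not.S (5.24, SE 0.35). Of 49 BMP genes 27 were lower and 5 higher, 30 and 5 adjusted over the list alone (median −0.95, adjusted p = 9.20e-08, or adjusted p = 0.0766 with an estimated correlation), as bmp7.1.S (−3.73, SE 0.17) and gata2.L (−3.56, SE 0.16). Of 36 endoderm genes 20 were lower and 1 higher, 22 and 1 adjusted over the list alone (adjusted p = 1.09e-06, or adjusted p = 0.0696 with an estimated correlation). Of 27 epidermal genes 19 were lower and 1 higher, 20 and 1 adjusted over the list alone (median −1.38, adjusted p = 3.23e-08, or adjusted p = 0.113 with an estimated correlation), their summed TPM being 7710 ± 2021. In all 4282 genes were higher and 6654 lower, and after median-of-ratios scaling, which moved the median of all genes from −0.16 to −0.06, 5288 and 5331.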

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

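The splits of libraries and the tests on BIO were planned before the counts were seen. The tests on dkk1 and the epidermal genes were chosen after the result was seen, as were, for BIO, the left-out libraries, the pairs kept from the choice of genes and the shares without room. Hindgut minus foregut effects of a treatment were tested as interactions. The 23 named genes given here passed, and the 3 counts have no p-value.

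The BIO interaction had 239 genes. Those given here with a higher effect in hindgut are pitx1.L (6.59), cyp26c1.S (5.36), cyp26c1.L (2.41), spib.L (4.79) and spib.S (4.11). Those with a lower effect are sp5.L (−4.07), sp5.S (−3.94), cdx2.S (−3.79), cdx2.L (−2.95), cdx4.L (−3.72), cdx4.S (−3.35), hes2.L (−3.49), axin2.L (−2.70) and cdx1.S (−2.88). The DMH1 interaction had 43 genes, with a higher effect for gprc5a.L (4.41, lost from foregut), tbx6r.L (4.17), lhx1.S (3.39), lhx1.L (2.93), foxd4l1.1.S (3.14) and foxd4l1.1.L (2.54). A lower effect had neurog1.L (−2.90), etv2.L (−2.57) and neurod1.S (−2.36). The Dkk1 heat shock interaction had 4 genes. Without 1 library at a time cyp26c1.L, hes2.L, foxd4l1.1.L and etv2.L lost their calls at least once.

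The first pattern is that BIO changed 1855 genes in foregut and 8 in hindgut. With the replicate block they were 3348 and 148, and without the germ layer libraries hindgut had 65. Larger spread between hindgut replicates could cause this gap. But the residual SD was 1.08 times that of foregut, or 0.999 to 1.22 with 1 of 12 libraries left out, under the planned limit. Genes raised by BIO could already be high in hindgut. This was set as a hindgut vehicle level over 2 times that of foregut, whatever the TPM. It held for 52.1% of the 238 that rose at least 2-fold. The other 114 had a hindgut median of 0.19 (95% interval 0.12 to 0.28) against 1.42 in foregut. Genes chosen without 1 pair of foregut libraries had 1.09 to 1.30 in that pair and 0.03 to 0.25 in hindgut. For fits to each region alone the ratio argues against larger spread. The 114 were chosen as not already high, and their change was still smaller in hindgut. Genes near 0 in hindgut may have had no room to fall, and 61.6% of the 859 that fell had none. The 330 with room fell by a median of −0.45 in hindgut (−0.49 to −0.39), above the planned limit of −0.62. That limit rests on the libraries that chose the genes. With pairs 1, 2 and 3 kept from the choice it was −0.50, −0.54 and −0.67, and the hindgut intervals were −0.52 to −0.40, −0.51 to −0.38 and −0.52 to −0.38. Chosen as having room, these genes had intervals over genes above the limit for pairs 2 and 3, not 1. Lack of room stays open for the 61.6%, and a high level for the 52.1%. Whether the regions differ in competence for Wnt was not tested.

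The second pattern is that dkk1 was not higher in the libraries labelled Dkk1 heat shock. Exchanged labels could cause this, but genes raised by BIO had a median of −0.23 there, the direction of lowered Wnt activity. Transgene reads may not be counted under dkk1, but with 0 features named for GFP this could not be tested. The pulse might act through heat, and with a lowest adjusted p of 0.159 for the heat shock list this stays open. No biological explanation was tested.

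The last pattern is that epidermal genes were higher in mesoderm than in endoderm libraries. Surface ectoderm left on the mesoderm pieces could cause this, and their summed epidermal TPM was at least 1.18 times that of unheated whole pieces. TPM composition might raise the list, but its lowest median after scaling was 4.89, so the tables argue against it. How much ectoderm each piece held stays open, and no biological explanation was tested.

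Other splits of the same libraries were counted in each case where enough exist. With 3 and 3 libraries only 10 splits exist, too few to exclude chance. The split by treatment had the highest count for hindgut against foregut vehicle (2155, next 2), FG_DMH1 (213, next 89), HG_DMH1 (336, next 2) and FG_BIO (1855, next 18), and 1 split of 10 reached it. For HG_BIO 2 of 10 splits reached the real 8, the highest other having 11. Dorsal against pooled vehicle gave 10299 genes, reached by 1 of 84 splits of its 9 libraries (highest other 3530), which argues against chance. It does not tell tissue from vehicle.

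For the interactions, regroupings within a region were drawn. The 43 genes of DMH1 were reached by 9 of 100 (highest other 632) and the 239 of BIO by 13 of 100 (highest other 998), so chance is not excluded for either count. All 12 others for BIO kept the foregut treatment groups intact, and the highest among regroupings that kept neither was 32. For DMH1 that figure was 572. Such splits could carry a real treatment effect into the interaction, so the count is a weak test.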

How the results depend on the processing

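The settings chosen after seeing the data are those named as such above. Unless a smaller number of libraries or genes is itself the change, the cause was not tested.

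Counts of called genes that moved by more than 1.5 times follow by setting. A pseudocount of 0.1 gave 99 for FG_DMH1, 217 for HG_DMH1, 5 for HG_HSdkk1, 10 and 143 for the DMH1 and BIO interactions, and 4 higher and 39 lower genes shared by both inhibitors. A pseudocount of 5 gave 372 for FG_DMH1, 24 for HG_BIO, 88 and 1 for the DMH1 and heat shock interactions, and 14 and 159 shared. No filter gave 14 for HG_BIO, 31 for FG_HSdkk1, 25 for HG_HSdkk1 and 27 for the heat shock interaction, and a filter at 5 TPM gave 1 for each of the last 3. Median-of-ratios scaling gave 10 for HG_HSdkk1 and 26 for the DMH1 interaction. Homeologs summed gave 121 for FG_DMH1, 203 for HG_DMH1, 158 for the BIO interaction and 65 lower genes shared. The replicate block gave 497 for FG_DMH1, 669 for HG_DMH1, 3348 for FG_BIO, 148 for HG_BIO, 1143 for HG_meso against FG_meso, 78 and 381 for the DMH1 and BIO interactions, and 26 and 193 shared.

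A fit to the groups compared alone has fewer libraries. It gave 841 for hindgut against foregut vehicle, 2 for FG_DMH1, 34 for HG_DMH1, 1114 for FG_BIO, 863 and 4600 between the layers of foregut and hindgut, 21 for the DMH1 interaction, 0 and 2 shared, and 0 for HG_BIO, for each heat shock comparison and their interaction, for unheated hindgut against foregut and for either layer of hindgut against foregut. Without the number 1 libraries hindgut against foregut vehicle had 1278, FG_BIO 1119, HG_BIO 5, the DMH1 interaction 19, and 15 and 48 were shared. Without FG_endo replicate 1 HG_BIO had 43 and HG_meso against FG_meso 1039. Without the germ layer libraries HG_BIO had 65, and 15 higher genes were shared. With the vehicle divided, FG_DMSO replicate 1, 2 or 3 alone for DMH1 gave 2, 4 and 4 higher and 31, 23 and 47 lower genes shared, and alone for BIO 3, 4 and 7 higher and 61, 52 and 38 lower.

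With 1 library left out at a time, counts ranged from 1463 to 1872 for hindgut against foregut vehicle, 115 to 359 for FG_DMH1, 140 to 406 for HG_DMH1, 1041 to 1855 for FG_BIO, 1 to 25 for HG_BIO, 3 to 20 for FG_HSdkk1, 0 to 15 for HG_HSdkk1 and 224 to 298 for unheated hindgut against foregut. They ranged from 5693 to 9386 between the layers of foregut, 7680 to 8326 between those of hindgut, 3739 to 8617 between endoderm, 363 to 479 between mesoderm and 8295 to 10913 for dorsal tissue. The interactions had 18 to 47 for DMH1, 187 to 241 for BIO and 1 to 8 for heat shock.

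Lists past the camera test numbered 10 for HG_BIO, and 5 in a fit to its groups or without the number 1 libraries. They were 13 for HG_endo against FG_endo and 8 with homeologs summed. With 1 library left out the lists ranged from 5 to 11 for HG_BIO, 7 to 12 for HG_HSdkk1 and 2 to 9 for the heat shock interaction.

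The set of hindgut-high genes in HG_BIO (median −0.10) lost its call after scaling (−0.11), with homeologs summed (−0.12), with the block (−0.064) and without the germ layer libraries (−0.076), and ranged from −0.30 to 0.16 with 1 library left out. In FG_DMH1 that set had a median of 0 and lost its call with the block (0), ranging from −0.063 to 0. Foregut-high genes in FG_DMH1 (−0.19) lost their call without the number 1 libraries (0, leaning higher) and without FG_DMSO replicate 1 (−0.070), in a range from −0.33. In HG_DMH1 they ranged from 0.00011 to 0.16, and hindgut-high genes from 0.064 to 0.53, each losing its call once. The other sets kept direction and call. All this is at the preset correlation. With an estimated one 4 of 14 sets passed, foregut-high genes in FG_BIO, both BIO sets in FG_HSdkk1 and hindgut-high genes in HG_HSdkk1, while the others had adjusted p from 0.0811 to 0.523.

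With homeologs summed ntn1.S turned to −0.79 in hindgut against foregut vehicle and krt5.7.S to −0.094 in HG_endo against FG_endo. The hindgut and tail bud list in HG_DMH1 leaned to lower values in the camera test despite a median of 0.24, and leaned to higher values without the number 1 libraries (0.48) and without HG_DMSO replicate 1 (0.52), with a range from −0.053 to 0.52. With 1 library left out, 8 more list values turned. Without HG_DMSO replicate 1 these were, in HG_BIO, hindgut and tail bud (range −0.53 to 0.11), Hox groups 6 to 13 (−0.77 to 0.16), FGF (−0.47 to 0.059) and paraxial mesoderm (−0.30 to 0). Hox groups 6 to 13 in HG_DMH1 turned without HG_DMSO replicate 2 (−0.083, range to 0.60). Paraxial mesoderm turned in FG_HSdkk1 without FG_HSdkk1 replicate 1 (0.10, range −0.47 to 0.14) and in HG_HSdkk1 without 1 unheated library (0, from −0.81), and FGF there without 1 heated library (0.013, from −0.62).

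Other values were steadier: for named genes 13747 values under other settings kept direction and call, 711 lost a call, 196 gained one and 11 moved. With 1 library left out 8458 kept it, 367 lost it, 65 gained one and 29 moved. List values kept it in 3142 cases and 1836 with 1 library left out, lost it in 141 and 130 and gained it in 76 and 104. In the foregut heat shock, where a pairing by number was used, the block gave 6 called genes. The hindgut heat shock columns, whose numbers match no sample, could not be paired. The unknown depth limits what a value near 0 can show.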

Other observations

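The myeloid factor spib.L stood at 121.7 TPM in FG_meso, 82.4 in unheated foregut and 43.5 in FG_endo, and at 0.585, 0.38 and 2.30 in the matching hindgut groups. Its level was lowered by BIO in foregut to 2.48 TPM. The enzyme cyp26c1.S, which clears retinoic acid, stood at 90.4 TPM in FG_DMSO but at 6.85 in unheated foregut, while dorsal tissue had 35.0.

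Of the posterior Hox genes hoxa7.L had 54.4 TPM in HG_endo and 72.1 in HG_meso, hoxb9.S had 37.1 and 96.8, and hoxd11.S, listed at 0 in HG_endo, had 15.8 in HG_meso. Endoderm and mesoderm differed between regions in the same direction for 292 genes called in both and in the opposite direction for 33. Between layers 4991 genes were called in the same direction in foregut and hindgut and 223 in opposite directions.

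The library FG_endo replicate 1 had the fewest features at 1 TPM (15182), the lowest size factor (0.55) and the lowest mean correlation with its group (0.915). In the heat shock experiment 1 unheated and 1 heated hindgut library held 14.8% and 15.7% of their TPM in their 10 highest features, against 7.39% and 7.22% in the other 2.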
